A study of Homo sapiens with 8 samples.

How the data were processed

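RNA of HCT116 cells expressing OsTIR1 was sequenced in 8 samples, 2 clones for each combination of tagged subunit (SA1-AID or SA2-AID) and treatment (500 µM auxin or solvent, 12 h), per the labels' protocols. Libraries were made with a stranded poly(A) protocol from 200 ng of total RNA and sequenced as single reads of 50 bp, per the labels' protocols. Per the submitters' processing notes, STAR, featureCounts and DESeq2 were used, with genome build hg19. Their versions, the strand setting and the gene annotation are not given in the sources used here. Clones are separate lines derived from single cells, and the labels do not state whether cultures of 1 clone with and without auxin were grown side by side.

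The authors deposited 1 table for each line, listing only genes that passed a threshold. The authors' mean signal, headed baseMean, is a mean of normalised read counts over the libraries. The log2 fold change of auxin against no auxin is as deposited, per the file headers. The p-value of each gene is as deposited, per the file headers, and the title line names an FDR. No value per library was used, so depth per sample is unknown, no model was fitted, and no library could be left out. The title line also says that genes known to respond to auxin are marked by a colour, and that marking was not used here.

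The 177 entries for SA1 had mean signals from 27.9 to 101646 in the authors' deposited table, and the 178 for SA2 from 15.9 to 38620. The smallest absolute log2 fold change in the authors' deposited tables was 0.15 for SA1 and 0.11 for SA2. Standard errors were derived by dividing the absolute log2 fold change by the normal quantile of the p-value, which assumes unadjusted two-sided Wald p-values. They had a median of 0.103 for SA1 and 0.115 for SA2, and they are printed only as implied values. They fall with the mean signal where counting error rises. At the lowest mean signals, 27.9 for SA1 and 15.9 for SA2, they were 0.059 and 0.0531, against a counting error of at least 0.273 and 0.362 for 2 libraries in each group. They lay below that error in 17 SA1 and 14 SA2 entries. Such values occur where fold changes have been shrunken towards 0, a step that the sources used here do not state, so the fold changes and implied errors are not read as plain ones.

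Genes were identified by the names in the tables. For SA1, 172 of 177 entries had an identifier of the named gene by GENCODE 29 or by the synonyms of a RefSeq gene table (assembly GRCh38.p14), of which no coordinates were used. Another 4 had an identifier that disagreed with the name, and 1 had none. For SA2, only 37 of 178 identifiers belonged to the named gene, while 138 of the 141 others belonged to another gene named in the same table. All 37 matching entries are genes also listed for SA1, so the identifiers bear out no gene listed for SA2 alone. Names were used for the SA2 values, because among 140 mismatched entries those with non-coding names had a median mean signal of 122 against 1083 for coding ones (permutation p = 3e-05), and the split by identifier gave 891 against 1082 (permutation p = 0.508). The name FGF9 occurs more than once for SA2. The entry carrying another gene's identifier was left out of the gene lists, the overlap and the GC comparisons, and kept in the totals, the comparisons of fold size and the reading of the p column. Its identifier is that of FUCA1, which is listed as higher for SA1, and its mean signal was 981 against 205 for the other FGF9 entry. It may thus be FUCA1, at a log2 fold change of 0.29, and so a further shared gene.

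Because the reference held here is GENCODE 29 on GRCh38 and the authors' build was hg19, no coordinates are given. The reference served for biotypes, for transcript GC content and length, as the median over a gene's coding transcripts or over all where none is coding, and for which genes neighbour or overlap each other. GC content was found for 177 of 177 SA1 entries and 177 of 178 SA2 entries. The planned test of clustering within 100 kb, with its alternatives, was not run, and a test on gene order took its place, in which the listed genes, with their signs, were placed at random among 19849 protein-coding genes 10000 times, within 10 classes of GC content.

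Before the data were examined, 28 gene lists, the tests and the rule for named genes were fixed. Named genes are the 10 highest and 10 lowest by log2 fold change, the 5 smallest p-values, cohesin list members, up to 15 shared genes by the larger p, and up to 4 members of each list with at least 3, with members of smaller lists named together. Some genes that the rule selects are not reported here. Other genes that complete a small count were named after their values were seen. Counts were compared with exact binomial and Fisher's exact tests, overlap with the hypergeometric distribution, and medians and correlations with 100000 permutations, all two-sided except the overlap. Adjustment was by Benjamini-Hochberg at 0.05. The count adjusted over the list alone gave unlisted members a p of 1. The planned tests on counts per sample were not possible with these tables, and the authors' own values took their place.

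Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and, for the figures, Matplotlib 3.10.9. The procedures were tested on simulated data. In 50 simulated tables of 15000 genes for each comparison, the rank correlation of implied standard error with p had a median of 0.068 for SA1 and 0.059 for SA2 when unadjusted p-values were read as such, and of 0.809 and 0.886 when adjusted values were read as unadjusted. At the size of each table, a GC shift of 5 percentage points was called in 81% of simulated cases for SA1 and 85% for SA2, and no shift in 6% and 8%. Alternatives covered the p threshold, the fold change, the mean signal, the biotype, the background and the way genes were matched.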

Results

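The series measured messenger RNA in HCT116 cells, an established human colorectal carcinoma line, that carry OsTIR1, a plant F-box protein which lets auxin trigger the destruction of a tagged protein. An auxin-inducible degron was fused to SA1 or SA2, the products of STAG1 and STAG2, which are alternative subunits of cohesin, the ring-shaped complex that folds chromatin into loops. The 8 libraries fell into 4 groups of 2: SA1-AID cells (clones 2 and 3) with and without auxin, and SA2-AID cells (clones 1 and 2) with and without auxin. Auxin was given at 500 µM for 12 h, and the cells without it received the solvent. The values are the authors' own comparisons of auxin against no auxin within each line, so no value per library was used and the depth of each library is unknown. The question behind both comparisons was which transcripts change when either cohesin subunit is removed.

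In SA1-AID cells the genes with the largest changes were higher after auxin. CYP1A1, a cytochrome P450 that oxidises aromatic compounds, was listed at a log2 fold change of 0.92, and HAS3, a hyaluronan synthase, at 0.91 in the authors' deposited table for SA1. The authors' deposited table further gave ALDH1A3, which makes retinoic acid, at 0.72 and AHRR, the repressor of the aryl hydrocarbon receptor, at 0.68. In the same authors' deposited table the lowest value belonged to PPIAP29, a processed pseudogene of cyclophilin A, at -0.49, and RRM1, the large subunit of ribonucleotide reductase, was at -0.28. Of the 177 genes in the authors' deposited table for SA1, 113 were higher after auxin and 64 were lower. That put 63.8% of them on the higher side (exact 95% interval 56.3% to 70.9%, two-sided exact binomial p = 0.000285). The interval and test, like those for SA2 below, take genes as independent and do not measure variation between clones. Among the 140 SA1 genes not also listed for SA2, 81 were higher and 59 lower, a split that was not tested.

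The remaining genes at the top of the SA1 comparison were TIPARP, an ADP-ribosyltransferase, at 0.51, the unnamed transcript AC015712.2 at 0.49, GDF15, a stress-induced cytokine, at 0.47 and LGALS3, a galectin, at 0.46 in the authors' deposited table. GDA, a guanine deaminase, followed at 0.45 and HPCAL1, a calcium sensor, at 0.44 in the authors' deposited table. Further down the authors' deposited table, the ribosomal protein genes RPSA and RPS29 stood at -0.28 and -0.26, CAV1, the main protein of caveolae, at -0.26 and RANBP1, a partner of the nuclear transport GTPase Ran, at -0.26. The processed pseudogene AC026366.1, the antisense transcript AC074033.1 and the processed pseudogene AC136632.1 were also among the 10 lowest genes. Their log2 fold changes were -0.28, -0.27 and -0.27 in the authors' deposited table. By identifier, AC026366.1 and AC074033.1 carry the ribosomal protein pseudogene symbols RPS2P5 and RPL22P1. The median absolute log2 fold change over the authors' deposited table for SA1 was 0.24, or 1.18-fold. The size of these values is uncertain, since the implied standard errors of all 7 SA1 entries and all 7 SA2 entries with a mean signal under 100 lie below the least error that counting allows, so the deposited fold changes look shrunken towards 0. Read as unadjusted Wald p-values, the authors' p-values imply a standard error of 0.10 to 0.11 for CYP1A1, HAS3 and AHRR.

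Among the gene lists fixed before the data were examined, targets of the aryl hydrocarbon receptor, a ligand-activated transcription factor, were listed only as higher in SA1-AID cells. The 6 members in the authors' deposited table were CYP1A1, AHRR, TIPARP at 0.51, CYP1B1 at 0.40, NQO1, a quinone reductase, and SLC7A5, an amino acid transporter. All 6 passed when adjusted over the list alone, which has 15 genes, and 5 passed Benjamini-Hochberg adjustment over an assumed 15000 tested genes. Set against the rest of the authors' table, their 6 of 6 gave a two-sided Fisher's exact p of 0.0883 (0.106 after Benjamini-Hochberg adjustment over 6 lists). No split of 6 genes goes further to the higher side, so the test could not have called them higher.

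Genes of cell division were listed as lower in SA1-AID cells. Of the G2/M list, 5 genes were lower and 0 higher, among them UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, at -0.25, CDK1, the mitotic kinase, at -0.24, CCNA2, cyclin A2, at -0.23 and BUB1B, of the spindle checkpoint, at -0.22 in the authors' deposited table. Of the G1/S and replication list, 5 genes were lower and 0 higher, with RRM1 at -0.28, the thymidylate synthase gene TYMS at -0.23, and the replicative helicase subunits MCM2 and MCM4 both at -0.20 in the authors' deposited table. Each list differed in direction from the rest of that table (two-sided Fisher's exact p = 0.00558, adjusted 0.0167 over 6 lists). No member of either list passed when adjusted over the list alone or over an assumed 15000 genes. Fisher's test takes the genes of a list as independent, and at p under 0.01 the call was lost for both lists, with 0 G2/M genes and only RRM1 of the G1/S list left.

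The ribosomal protein list, taken by symbol, held 7 genes, of which 6 were lower and 1 higher (two-sided Fisher's exact p = 0.0095, adjusted 0.019 over 6 lists). The lower members in the authors' deposited table were RPSA, RPS29, RPS23, RPL34 and RPL5P4, at -0.23, and RPS27AP16, which carry pseudogene symbols. The higher member, RPS6KA2 at 0.30 in the authors' deposited table, is a protein kinase caught by the symbol and not a ribosomal protein. Reads of ribosomal protein genes and their processed pseudogenes are nearly identical, so single members are uncertain. Lower SA1 genes as a whole had shorter transcripts than higher ones, with medians of 940.2 and 1990 nt (permutation p = 4e-05), and ribosomal protein genes such as RPS29 are short. When adjusted over the list alone, 0 of the 7 passed.

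Hypoxia and glycolysis genes were listed as higher in SA1-AID cells, with NDRG1 at 0.32, the glucose transporter SLC2A1 at 0.29 and the mitophagy receptor BNIP3L at 0.29 in the authors' deposited table. All 3 passed when adjusted over the list alone and 0 over an assumed 15000 genes. The test of their direction could not have passed with 3 genes, all of them higher (two-sided Fisher's exact p = 0.554, adjusted 0.554 over 6 lists). The 6 solute carriers in the authors' deposited table were also higher, led by SLC7A5 at 0.32 and its partner SLC3A2 at 0.31, then SLC2A1 at 0.29 and SLC37A2 at 0.22 (two-sided Fisher's exact p = 0.0883, adjusted 0.106). With all 6 higher, this test too could not have given a smaller p on that side. Of these solute carriers, 0 passed when adjusted over the list alone.

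Smaller lists had 1 or 2 members in the SA1 comparison. The authors' deposited table held the p53 targets GDF15 and FUCA1, at 0.47 and 0.33, and the stress genes STC2 and SLC3A2, at 0.43 and 0.31. It also held the phosphatase DUSP4 at 0.33, the intestinal stem cell factor SOX9 at 0.25 and the keratin KRT15 at 0.26, while the small heat shock protein HSPB1 stood at -0.22 in the authors' deposited table. Adjusted over the list alone, both p53 targets, both stress genes and DUSP4 passed, and SOX9, KRT15 and HSPB1 did not. Among cohesin subunits and regulators only CDCA5, the gene of sororin, was in the authors' deposited table, at -0.21, and it did not pass when adjusted over its list alone. STAG1 itself, the degron target, was not among the 177 genes, nor was STAG2.

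In SA2-AID cells CYP1A1, AHRR and HAS3 again led the increases. Genes named for SA2 and not for SA1 rest on the name column, since their identifiers do not match their names. The authors' deposited table for SA2 gave CYP1A1 a log2 fold change of 0.65, AHRR 0.61, HAS3 0.52 and the unnamed transcript AC026254.2 0.50. The ubiquitin ligase gene TRIM2 followed at 0.49, GDA at 0.45 and NR4A2, an orphan nuclear receptor, at 0.44 in the authors' deposited table. The lowest values in the authors' deposited table were those of TGM2, a transglutaminase, at -0.45, AMOTL2, an angiomotin family member, at -0.38 and PIDD1, a death-domain protein, at -0.31. Of the 178 entries in the authors' deposited table for SA2, 89 were higher and 89 lower (50%, exact 95% interval 42.4% to 57.6%; two-sided exact binomial p = 1). The balance depended on which entries were kept, with 54 higher and 79 lower when the entries of lowest mean signal were left out, which kept 133 (two-sided exact binomial p = 0.037) and 22 higher and 9 lower at p under 0.01 (two-sided exact binomial p = 0.0294). Among the 141 SA2 entries not shared with SA1, 57 were higher and 84 lower, a split that was not tested.

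The other low genes of the SA2 comparison included the actin crosslinker FLNC at -0.31, F3, tissue factor, at -0.29 and the proteoglycan GPC1 at -0.29 in the authors' deposited table. UBE2C at -0.30, NDUFB7, of respiratory complex I, at -0.30 and the adaptor SH2D3A at -0.29 were further low genes in the authors' deposited table. TIPARP, CYP1B1 and NQO1 were among the 10 highest, at 0.43, 0.43 and 0.41 in the authors' deposited table. The median absolute log2 fold change was 0.25, which was 0.01 larger than for SA1 (two-sided permutation p = 0.0222). Both tables hold only genes under a p threshold, and the implied standard errors had a median of 0.115 for SA2 and 0.103 for SA1, so the smallest change that can be listed differs and that difference is no measure of a larger effect.

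Aryl hydrocarbon receptor targets were again listed only as higher, with 5 of 5 members of the list in the authors' deposited table for SA2. All 5 passed when adjusted over the list alone and 2, CYP1A1 and AHRR, over an assumed 15000 genes. Their direction gave a two-sided Fisher's exact p of 0.0286 (adjusted 0.0573 over 2 lists). With all 5 higher, no smaller p was possible on that side, so the test could not have passed after adjustment. The 3 solute carriers, SLC2A13, SLC3A2 and SLC1A1, were each at 0.24 in the authors' deposited table, with 0 passing when adjusted over the list alone. Their direction gave a two-sided Fisher's exact p of 0.121 (adjusted 0.121 over 2 lists), and 3 genes, all higher, could not have given a smaller p on that side.

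Lists with 1 or 2 members in the SA2 comparison went both ways. The growth-factor-induced transcription factor genes FOS and EGR1 stood at 0.40 and 0.26, the hypoxia genes KDM3A and NDRG1 at 0.30 and 0.24, and INSIG1, a regulator of sterol synthesis, at 0.25 in the authors' deposited table. GDF15 was at 0.22 and SLC3A2 at 0.24 in the authors' deposited table, and the ribosomal list held RPL39 at 0.27 and the pseudogene RPL31P2 at 0.29. Lower were the mitotic genes UBE2C and AURKB, the latter at -0.28, the keratins KRT7 and KRT8 at -0.28 and -0.22, the laminin gene LAMB3 at -0.24, the histone gene H2AFX at -0.24 and the rRNA processing gene RRP9 at -0.24 in the authors' deposited table. KRT8 is also the only member of the intestinal list, and RRP9 the only one of the MYC target list. Of all these, FOS alone passed when adjusted over its list alone. Neither STAG2 nor STAG1 was listed, and no cohesin subunit or regulator was.

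**Figure D1:**
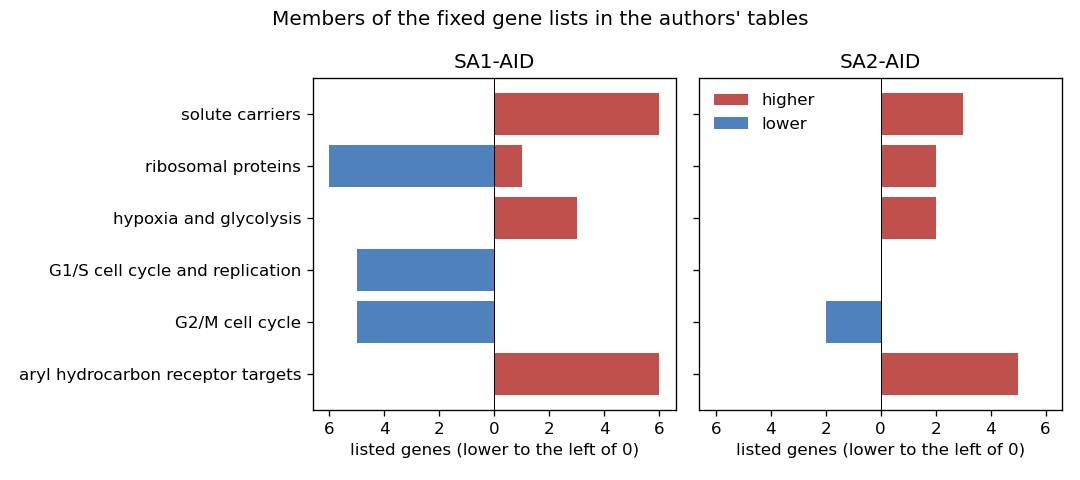
Number of genes of each fixed list with 3 or more members in at least 1 table, for SA1-AID (left) and SA2-AID (right); bars to the right of 0 count genes higher after auxin and bars to the left genes lower. The aryl hydrocarbon receptor list has 6 higher genes in SA1-AID and 5 in SA2-AID, and both cell cycle lists have 5 lower genes in SA1-AID.

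The level of evidence in both tables depends on how the p column is read. Its heading names a p-value, while the title line of each table names an FDR under 0.05 together with a log2 fold change over 0.6, a size that 4 genes in the authors' deposited table for SA1 and 2 in that for SA2 exceed. If the column holds unadjusted p-values from 15000 tested genes, an assumed number, Benjamini-Hochberg adjustment at 0.05 leaves 15 genes for SA1, of which 14 are higher, and 4 for SA2, all higher. These are the least numbers if genes with small p-values were left out of the tables. The 4 are CYP1A1, AHRR, HAS3 and AC026254.2. The identifier given for AC026254.2 is that of RPL34P31, which carries a ribosomal pseudogene symbol, so which gene this entry measures is uncertain.

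The SA1 and SA2 comparisons shared 37 genes by name, and all 37 had the same direction in both. They include CYP1A1, AHRR, HAS3, GDA, NQO1, CYP1B1, TIPARP, ALDH1A3, TRIM2, AC015712.2, CD109, a GPI-anchored surface protein, OR51B4, an olfactory receptor gene, FGF9 and MID1, a microtubule-associated ubiquitin ligase, all listed as higher in each of the authors' deposited tables. Higher in both were 32 genes, against 0.505 expected for independent lists among the 19684 genes with a protein-coding transcript in GENCODE 29, an assumed background. Lower in both were 5, against 0.289 expected, namely CAV1, UBE2C, GAL, TOMM40 and TPM2, the last 3 of which were picked out after their values were seen. The shared genes were 20.9% of each table, and 1.59 were expected in all (one-sided hypergeometric exact p = 2.51e-40). With a background of 10000 genes, 3.13 were expected. The shared direction gave a two-sided Fisher's exact p of 2.29e-06. The 2 comparisons used separate control libraries.

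Fold changes of the shared genes rose together across genes, which are not independent replicates, with Pearson's r = 0.907 (permutation p = 1e-05, the smallest the permutations can give) and Spearman's rho = 0.617 (permutation p = 8e-05). That value spans the gap between higher and lower genes, and within the 32 higher ones r was 0.729 (permutation p = 5e-05) and rho 0.408 (permutation p = 0.0212). Without CYP1A1 and HAS3, the pair farthest from the median in SA1, r fell to 0.546 (permutation p = 0.00335) and rho to 0.282 (permutation p = 0.131). Of the 32, 22 had the larger fold change in SA1-AID cells and 10 in SA2-AID cells (two-sided exact binomial p = 0.0501). For HAS3 the difference between the authors' deposited tables was 0.39 (95% interval 0.10 to 0.69 from the implied standard errors) and for ALDH1A3 0.35 (0.06 to 0.63), values that also depend on how each table was shrunken, and neither passed Benjamini-Hochberg adjustment over the 37 genes (adjusted 0.304 each, from the authors' values).

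**Figure D2:**
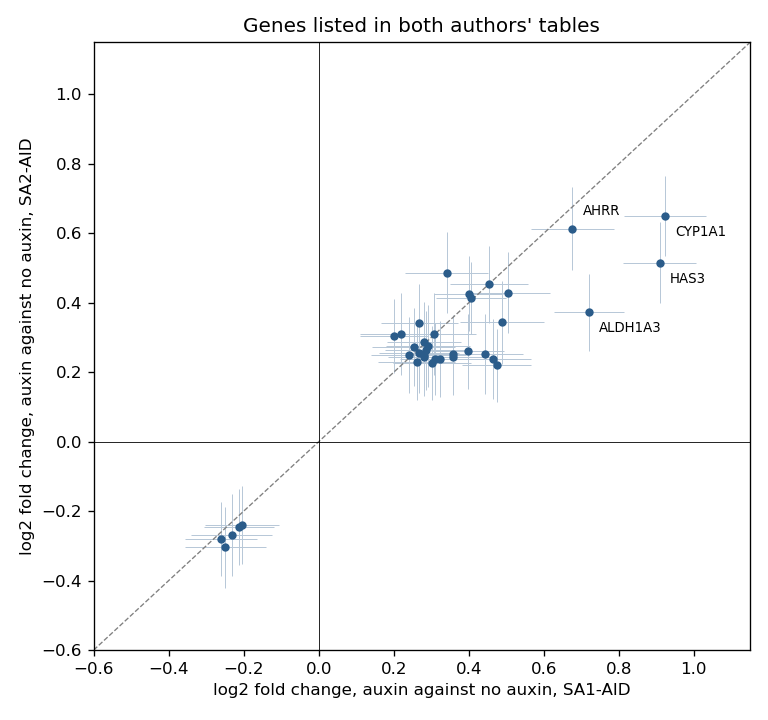
Log2 fold change, auxin against no auxin, of the 37 genes listed in both of the authors' deposited tables, SA1-AID on the horizontal axis and SA2-AID on the vertical axis; bars are the standard errors implied by the authors' p-values read as unadjusted, and the dashed line marks equal values. All 37 points lie in the quadrants of equal direction, with CYP1A1 at 0.92 and 0.65 and HAS3 at 0.91 and 0.52.

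Genes listed for SA1 alone and for SA2 alone, with 140 gene names in each, were compared for the 8 of 28 fixed lists with at least 3 members among them. None passed, but for most lists the outcome was set by their size. The most extreme split of 5 genes, 5 against 0, gives a p over 0.05, so lists of 5 or fewer could not pass. Adjustment over 8 lists asks for a smaller p still, and only the ribosomal list was large enough to reach it. The G1/S and replication list had 5 genes on the SA1 side, RRM1, TYMS, MCM2, MCM3 and MCM4, and 0 on the SA2 side (two-sided Fisher's exact p = 0.0603, adjusted 0.482 over 8 lists). The ribosomal list had 7 against 2 (two-sided Fisher's exact p = 0.173, adjusted 0.69) and the G2/M list 4 against 1 (two-sided Fisher's exact p = 0.37, adjusted 0.894). Solute carriers numbered 5 against 2 (two-sided Fisher's exact p = 0.447, adjusted 0.894), and the hypoxia, immediate early, matrix and keratin lists each gave a two-sided Fisher's exact p of 1.

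Genes listed in both comparisons had larger changes than the others. Their median absolute log2 fold change was 0.31 against 0.23 for the other genes of the SA1 table (permutation p = 1e-05, the smallest the permutations can give) and 0.27 against 0.25 for the other entries of the SA2 table (permutation p = 0.00214). Among the 20 genes with the smallest p in the authors' deposited tables, 15 of those for SA1 and 12 of those for SA2 were shared. These values are partly built in, since a shared gene had to pass a p threshold in both comparisons and larger changes pass more readily. Of the 15 SA1 genes that passed adjustment over an assumed 15000 genes, 13 were shared, and the others were PPIAP29 and STC2. No untagged cells given auxin were among these samples, so responses to auxin and to loss of a subunit were not separated.

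Lower genes of the SA2 comparison, such as TGM2, FLNC and KRT8, had GC-rich transcripts, with a median GC content of 62% against 45% for the higher genes (permutation p = 1e-05, the smallest the permutations can give). In the SA1 comparison the medians were 49.5% for lower and 52.3% for higher genes (permutation p = 0.05004), and among protein-coding genes alone the difference of higher minus lower was 2.91 points (permutation p = 0.0423). With SA2 values assigned by the identifier column in place of the gene name, the SA2 difference was -6.44 points (permutation p = 0.0508). Over the mismatched entries alone, where that choice matters, it was -18.8 points by name and -3.86 by identifier (permutation p = 0.239 by identifier). The SA2 difference thus rests on the name column.

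**Figure D3:**
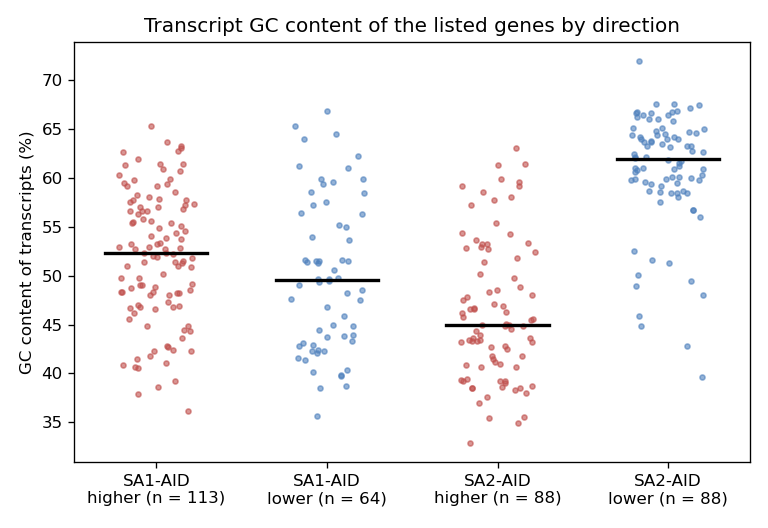
GC content of transcripts, in percent, of the genes higher (red) and lower (blue) after auxin in each of the authors' deposited tables; each point is a gene and the black line is the median. Lower SA2-AID genes centre on 62% and higher ones on 45%, while the SA1-AID medians are 49.5% and 52.3%.

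The lists with no member in either of the authors' deposited tables were those of interferon response, NF-kB and inflammatory targets, TGF-beta and BMP targets, clustered protocadherins, HOX genes, ZNF genes, mitochondrially encoded genes, neuronal genes, immune cell markers, and endothelial and fibroblast markers. As the tables list only genes under a p threshold, absence from them does not show that a gene was unaffected.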

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

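The GC comparison, with its alternatives, was chosen after the tables had been opened, and its tests were written before their values were seen. Transcripts of genes higher and lower after auxin differed in GC content in SA2-AID cells and not in the same way in SA1-AID cells. In the SA2 comparison the lower genes, such as TGM2, FLNC and KRT8, had a median GC content of 62% and the higher ones 45%, while in the SA1 comparison the medians were 49.5% and 52.3%. The difference of higher minus lower was -17 percentage points for SA2 (permutation p = 1e-05, the smallest the permutations can give) and 2.8 for SA1 (permutation p = 0.05004), or 2.91 among protein-coding SA1 genes (permutation p = 0.0423). With values assigned by identifier the SA2 difference was -6.44 points (permutation p = 0.0508). Over the mismatched entries alone it was -18.8 points by name and -3.86 by identifier (permutation p = 0.239 by identifier), so it rests on the name column. The contrast between the tables, -19.8 points, was picked out because it was tested directly by permuting the tables within each direction (permutation p = 1e-04, the smallest 10000 permutations can give). Of the lower SA2 genes, 90.9% lay above the median of all protein-coding genes, 50.4%, against 27.3% of the higher ones.

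A bias with transcript length as the cause is argued against, since the GC difference was 15.4 points or more, lower above higher, among both the shorter and the longer transcripts. A GC bias between libraries may account for it, but the 17 points of lower minus higher are the pattern itself, and no values per library were used that could test that bias. Loss of SA2 acting on GC-rich genes predicted a difference under 2 points in the SA1 table, where lower minus higher was -2.8 points, larger than that bound and opposite in sign. These explanations cannot be told apart here.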

How the results depend on the processing

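No paired analysis was possible because the tables carry no values per library, which also ruled out leaving out a clone, a replicate block, pseudocounts, other size factors and another count filter. A p threshold of 0.1 added no gene, since none above 0.05 is listed, and clustering by distance, with its alternative distances, was not run for want of coordinates on the authors' build. Settings with 15000 or 10000 assumed genes for adjustment, matching by identifier, GC alternatives and overlapping neighbours were chosen after seeing the data. Counts fell with stricter thresholds by construction. For SA1, 63 genes (53 higher, 10 lower) had p under 0.01, 4 an absolute log2 fold change of at least 0.58, 0 of at least 1, 17 passed Bonferroni over the listed genes, and 15 and 16 passed Benjamini-Hochberg over 15000 and 10000 genes. For SA2 these counts were 31 (22 higher, 9 lower), 2, 0, 12, 4 and 4. Leaving out the lowest mean signals kept 133 entries in each, 80 higher and 53 lower for SA1 and 54 higher and 79 lower for SA2. Overlap fell from 37 to 13 at p under 0.01, to 2 at 0.58 and to 3 after Benjamini-Hochberg over 15000 genes, and was 38 by identifier, which is no independent check since matching identifiers are those of shared genes. The same-sign share was 100% in each subset, but with few lower genes left the test no longer passed at p under 0.01 (Fisher's exact p = 0.0769) or at 0.58 (Fisher's exact p = 1). The difference in median absolute fold change of SA1 minus SA2, -0.01, was -0.0321 at p under 0.01 (permutation p = 0.0873) and turned to 0.18 at 0.58 with 4 against 2 genes (permutation p = 0.133); the cause was not tested. The correlation of shared genes ran from 0.854 to 0.907. Gene lists with a direction of their own fell from 3 to 1 at p under 0.01 and stayed at 3 with older symbols. Between the tables, 0 of the lists with at least 3 members passed, in the main setting or at p under 0.01. For most of them the size of the list set that outcome. The SA2 GC difference of higher minus lower lay between -19.9 and -15.4 points by name, in subsets by p, biotype, transcript length, table and list, and was -6.44 by identifier (permutation p = 0.0508), where identifiers do not belong to the named genes, and that of SA1 lay between 1.96 and 5.67, passing among protein-coding genes (2.91, permutation p = 0.0423) and at p under 0.01 (5.67, permutation p = 0.0468) and in none of the 6 others; the cause was not tested. Over the mismatched SA2 entries alone, the GC difference was -18.8 points by name and -3.86 by identifier (permutation p = 0.239 by identifier). Adjacent SA1 pairs fell from 6 to 3 without overlapping genes (permutation p = 0.0192). Unknown depth limits what can be said of genes that are not listed.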

Other observations

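The tests of the p column and of the shared response, with the values on pseudogenes, transcript length and overlapping neighbours, were chosen after the result was seen. Pseudogenes listed for SA1 were mostly on the lower side, though PPIAP29 alone of them passed adjustment over an assumed 15000 genes. Of 13 pseudogenes in the authors' deposited table for SA1, 2 were higher and 11 lower, a split that differed from that of the other genes (two-sided Fisher's exact p = 0.000297). By identifier, 7 listed genes carry symbols of ribosomal protein pseudogenes and all 7 were lower; 5 of them, such as RPL5P4 and AC026366.1, are among the 13, and 2 are annotated with another biotype. In the authors' deposited table for SA2, 3 pseudogenes were higher and 2 lower (two-sided Fisher's exact p = 1). Lower SA1 genes also had shorter transcripts, with a median of 940.2 nt against 1990 nt for higher ones (permutation p = 4e-05), and of 1356 nt against 2018.5 nt among protein-coding genes (permutation p = 0.00952). For SA2 the medians were 1700.0 nt for lower and 2432.5 nt for higher protein-coding genes (permutation p = 0.073).

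Neighbouring genes were listed together for SA1 more often than in random draws, though none of the genes in these pairs passed adjustment over an assumed 15000 genes. Among 153 placed genes, 6 adjacent pairs of protein-coding genes were listed with the same sign, against a median of 0 and a 95th percentile of 2 in 10000 draws matched on GC content (permutation p = 1e-04, the smallest the draws can give). In the authors' deposited table for SA1 they were SOX9 with SLC39A11, ITPR1 with BHLHE40, TRIOBP with H1F0, HBE1 with OR51B4 and ARSG with SLC16A6, all higher, and EXOSC9 with CCNA2, lower, named after their values were seen. Annotated spans of HBE1 and OR51B4 overlap on the same strand, so reads could be shared. Those of ARSG and SLC16A6, and of EXOSC9 and CCNA2, overlap on opposite strands. Sharing there would need counting that ignores strand, a setting that is not given. Without overlapping pairs 3 remained (permutation p = 0.0192). The SA2 comparison had 2 pairs, CKB with TRMT61A and PJA2 with MAN2A1, against a median of 1 and a 95th percentile of 3 (permutation p = 0.309). The 6 pairs lay above the bound set for changes shared by neighbouring genes, and the 2 SA2 pairs between its bounds, so a hypothesis is that neighbouring genes may respond together in SA1-AID cells given auxin. Of the 6 pairs, 3 hold a gene that is also listed for SA2 (OR51B4, H1F0 and ITPR1), and loss of SA1 was not separated from auxin. The draws came from all 19849 placed protein-coding genes and not from expressed ones, which lie close together in the genome, so chance may give more pairs than the draws did.

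The shared higher genes form a pattern with competing explanations. Of the aryl hydrocarbon receptor targets in either table, 5 of 6 were in both, 83.3%, against 32 of 311 other genes, 10.3% (Fisher's exact p = 9.26e-05), and each was higher. The list was fixed before the data were examined, but this test was chosen once its members had been seen in both tables, and it describes the overlap without separating its causes. A response to auxin itself through that receptor, for which indole compounds can act as ligands, and loss of either cohesin subunit cannot be told apart here for any shared gene, as 0 untagged samples given auxin were among the samples used and the authors' colour marking of genes known to respond to auxin was not used here.

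The unit of the p column changes how many genes count as called. If it held Benjamini-Hochberg values of every call, standard errors from undoing the adjustment would depend little on p. In simulated tables of that kind, without shrinkage, their median rank correlation with p was 0.19 for SA1 and 0.153 for SA2. Over listed genes of mean signal 500 to 10000 it was -0.708 for SA1 and -0.565 for SA2, which argues against that reading. Read as unadjusted p-values the correlation was 0.222 for SA1 and 0.033 for SA2, and as the bound set was 0.2 in both tables, the SA1 value leaves that reading open. All 177 p-values for SA1 and all 178 for SA2 were distinct. Benjamini-Hochberg adjustment commonly gives ties, so this also argues against adjusted values. The tables hold at most 1.19% of an assumed 15000 genes, below the bound set for a list of every tested gene with p under 0.05. Unchanged genes alone would give 5% if their p-values were evenly spread. As the fold changes look shrunken, that spread cannot be assumed, so the count cannot decide whether every such gene is listed. How the listed genes were chosen is therefore not known.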
